A study of Mus musculus with 13 samples.

How the data were processed

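RNA was measured by sequencing in male primordial germ cells, the embryonic precursors of sperm, from mouse embryos at E14.5. Per the labels' protocols, the cells were sorted by an Oct4-GFP reporter, a fluorescent protein under control of a gene active in germ cells. Total RNA was taken from a small, fixed number of sorted cells, mRNA was captured on oligo-dT beads and libraries were made with a NEB Ultra II kit. Beads of this kind enrich polyadenylated RNA, so transcripts without a poly(A) tail are under-represented, and the small cell number limits how many molecules of a weakly expressed gene enter a library.

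The authors deposited whole-number read counts per gene symbol in 1 table of 35976 symbols, with no normalization. Per the submitters' processing notes, the tools were FastQC, Trim Galore 0.6.7, STAR 2.7.10b, SAMtools 1.9 and featureCounts 2.0.3. Those notes name the builds GRCm39 and mm10 with no role for either, and the annotation, the strand setting and any read filter are not given in the sources used here. Reads from overlapping or antisense genes, or from near-identical members of a gene family, therefore cannot be told apart in these counts. Of the columns with values per library, 12 carry the name of a sample, and 1 further column names no sample and was not used. A further wild-type sample is listed in the labels and was not analysed here, so each of the 4 genotypes had 3 libraries. The design fixed beforehand had counted that sample in, and all fits here used 12 libraries. A planned split of the WT libraries into equal parts was not run, because 3 libraries do not allow it.

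Library totals ran from 13584484 to 29641963 counts. The libraries WT, KO, HxD and V are named by genotype and by the replicate number of the labels. Nothing in the labels says that replicates came from separate animals or pools, so the p-values measure only the spread between these samples, which may be technical. No pair of libraries held identical counts. Spearman correlations of the counts were 0.928 to 0.963 within genotypes and 0.912 to 0.964 between them.

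Genes were kept with the default expression filter of edgeR, which left 14702 for testing. Counts were scaled by TMM, and edgeR's quasi-likelihood F-test was fitted to all 12 libraries with genotype as the only term. Every test was two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Values per library are CPM, read counts scaled to a common library total, after TMM scaling, and the log2 fold changes, standard errors and adjusted p-values come from this edgeR fit. The common biological coefficient of variation was 0.932, a large value that limits the changes that can be detected. All 6 pairs of genotypes were compared.

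The 26 gene lists were fixed before the data were examined, from general knowledge of germ cell biology, and 696 of their 701 symbols were found in the table. They covered DNA methylation enzymes, paternally and maternally expressed imprinted genes, germ cell genes with promoters known to be methylated in somatic cells, meiosis, the piRNA pathway, pluripotency, male germ cell fate, spermatogonia, spermatids, cell cycle, cell cycle arrest, p53 targets, glycolysis, TGF-beta and Nodal signalling, immediate-early genes, mitochondrially encoded genes, Y-linked genes and X inactivation. Others held markers of Sertoli, Leydig, interstitial, endothelial, macrophage, erythroid and granulosa cells. Lists share members, and 25 had at least 5 tested genes. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated per list and with fry. Summed CPM of a list were compared with an exact permutation test, which cannot go below 0.1 for 3 libraries against 3.

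Genes named in the text follow a rule fixed beforehand. It takes Tet1 always, the 8 called genes with the smallest p in each direction of each comparison with WT, and 4 in each direction between mutants. From each list it takes the 4 called members with the smallest p or, where none was called, 2 members as values. Predicted and unnamed gene models were left out. Genes outside this rule are marked as chosen after their values were seen.

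Alternatives fixed beforehand were RLE scaling, DESeq2, no expression filter, a stricter filter, fits on 2 genotypes only, a replicate block, 1 surrogate variable from svaseq, a minimum fold of 2 and leaving out each library in turn. Setting WT 3 and V 3 aside together was added after seeing the data. The effects stand in the closing section. Overlaps between comparisons that share the WT libraries were set against 50 simulations of unchanged groups.

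The tests were tested on simulated data before use. The simulated changed genes were drawn from those averaging at least 8 CPM, so recovery of weaker genes was not measured. For KO against WT with 14702 genes, edgeR recovered 48% of genes changed 2-fold and 73% of those changed 4-fold. It made 11 false calls there, and 0 calls in a comparison where nothing had been changed. DESeq2 recovered 56% and 79%, with 125 false calls and 62 calls where nothing had been changed. For that reason the higher DESeq2 counts given below are read with care. Camera called the simulated changed list and 0 of 20 unchanged lists. The simulated genes varied independently of each other, so this could not test the preset correlation for lists whose members vary together.

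Gene positions are those of GENCODE M21 on GRCm38, used for location and length only. Software versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0.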

Results

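Transcript levels were compared in E14.5 male primordial germ cells of 4 Tet1 genotypes, with 3 libraries each. TET1 is an enzyme that oxidises 5-methylcytosine in DNA, a step towards its removal. WT is the wild type and KO a knockout. HxD is known as an allele whose TET1 protein lacks catalytic activity, and V as one whose protein stalls at 5-hydroxymethylcytosine, the earliest oxidation product. The series as a whole concerns the catalytic activity of TET1, imprinting control regions and regions of low methylation in sperm, and these libraries give the transcript side of that question. Total counts ranged from 13584484 in V 3 to 29641963 in HxD 1. The number of genes with a count ranged from 11529 in WT 3 to 15715 in V 2. Among the 9271 genes averaging at least 8 CPM, 107 had a count of 0 in WT 3, against 37 in HxD 2, 36 in V 3 and 0 in WT 2 and KO 2. The first 3 principal components held 17.8%, 13.7% and 11.9% of the variance, with WT 3 far out on PC2 and V 3 on PC3.

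Tet1 (chromosome 10, 62804570 to 62908996, minus strand) had 608 ± 27.0 CPM in WT (SD, n = 3), 213 ± 11.8 in KO, 626 ± 101 in HxD and 480 ± 133 in V. The KO level was 2.86-fold lower than WT (log2 fold change -1.51, SE 0.17, edgeR adjusted p = 1.41e-05), and every KO library lay below every other library. The HxD level differed from WT by a log2 fold change of 0.04 (95% interval -0.31 to 0.39, edgeR adjusted p = 1), with its sign reversed to -0.09 without HxD replicate 2. The V value was -0.34 (SE 0.17, edgeR adjusted p = 0.821). The labels do not say which part of the gene the knockout lacks, so reads remaining in KO may come from outside it.

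**Figure D1:**
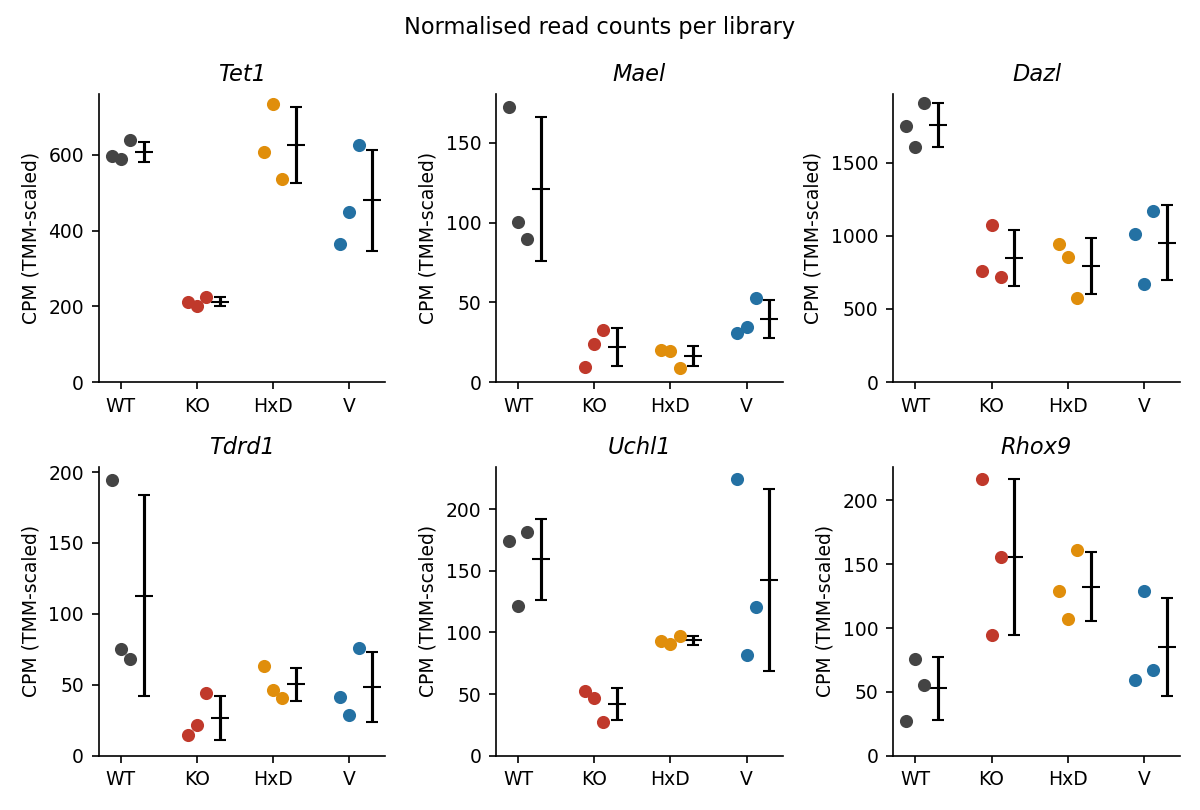
Normalised read counts (CPM after TMM scaling, linear axes from 0) of 6 genes in each library, with coloured points for libraries and black bars for the mean and SD of 3 libraries per genotype. Tet1 in KO averaged 213 CPM against 608 in WT, and Dazl averaged 1754 CPM in WT against 849 in KO, 793 in HxD and 953 in V.

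The comparison of KO with WT asks what the loss of TET1 does to transcripts in these cells. Mael (chromosome 1, 166201201 to 166238747), a piRNA pathway gene, had 22.1 ± 11.8 CPM in KO against 121 ± 45.2 in WT (log2 fold change -2.45, SE 0.39, edgeR adjusted p = 0.0018). Dazl (chromosome 17, 50279395 to 50293636), an RNA-binding regulator of germ cell development, fell from 1754 ± 150 to 849 ± 193 CPM (log2 fold change -1.05, SE 0.19, edgeR adjusted p = 0.00943). Tdrd1 (chromosome 19, 56826209 to 56870012), another piRNA pathway gene, fell from 113 ± 70.9 to 26.7 ± 15.5 CPM (log2 fold change -2.08, SE 0.40, edgeR adjusted p = 0.0127). Uchl1 (chromosome 5, 66676091 to 66687234), a deubiquitinating enzyme used as a spermatogonial marker, fell from a mean of 159 to 42.2 CPM (log2 fold change -1.92, SE 0.28, edgeR adjusted p = 0.000817). Epas1 (chromosome 17, 86753700 to 86833410), a hypoxia-inducible transcription factor, fell from 43.7 ± 7.33 to 4.76 ± 2.91 CPM (log2 fold change -3.20, SE 0.51, edgeR adjusted p = 0.0018). The kinase Sgk3 and the zinc finger gene Bnc2 also fell, with log2 fold changes of -1.81 and -2.17.

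Higher in KO were Lrrc34 (log2 fold change 2.65, SE 0.46), the receptor gene Notch1 (2.50, SE 0.54), the homeobox gene Mkx (1.60, SE 0.33), the X-linked homeobox genes Rhox9 (1.56, SE 0.31) and Rhox5 (0.89, SE 0.19), Tmem184b (1.22), Mfge8 (1.05) and the progranulin gene Grn (0.88). The Rhox genes form a multigene family, so their counts are uncertain where near-identical copies share reads. In all, edgeR called 10 genes higher and 22 lower among 14702, and 1220 had an unadjusted p under 0.05 where chance alone gives 735. DESeq2 called 212, and edgeR 148 without the low-count filter, 19 with a stricter one, 18 with 1 surrogate variable and 12 with these 2 genotypes alone. Other called genes included Smc1b, a meiotic cohesin gene (-1.01), Tex14 (-0.76), Rab3gap2 (-1.07), Pmaip1 (-1.05), the hedgehog receptor gene Ptch1 (-0.94) and Pdk1 (-0.96). The count moved to 15 without WT replicate 1, 95 without WT replicate 2, 73 without KO replicate 2 and 19 without KO replicate 3. Tet1, Uchl1, Sgk3, Mael and Epas1 were called under each of the 14 alternative settings run for genes. Calls ended for Notch1, Mfge8, Rhox5, Ptch1 and Pdk1 with the stricter filter, with 1 surrogate variable and with the 2 genotypes alone. Those of Tmem184b, Rhox9, Mkx and Tex14 ended in the last 2 of these settings. Smc1b lost its call in the first 2, and Tdrd1, Rab3gap2 and Pmaip1 with the 2 genotypes alone. Without WT replicate 1 the calls ended for Tdrd1 (adjusted p = 0.122), Rab3gap2 (0.0813), Tex14 (0.128), Smc1b (0.0728), Pmaip1 (0.0977), Ptch1 (0.126), Pdk1 (0.0924), Grn (0.0799), Mkx (0.0792), Mfge8 (0.0562) and Rhox5 (0.159). Without WT replicate 3 they ended for Tmem184b (0.0699), Grn (0.0572), Mkx (0.0847), Mfge8 (0.173), Rhox5 (0.0835), Tex14 (0.0835), Smc1b (0.0772) and Ptch1 (0.0764). Without KO replicate 1 they ended for Lrrc34 (0.0517), Rhox9 (0.0561), Notch1 (0.0515), Rhox5 (0.0817), Tex14 (0.117), Pmaip1 (0.0515), Ptch1 (0.156) and Pdk1 (0.173). Without KO replicate 2 the call of Tex14 ended (0.0717). With WT 3 and V 3 set aside together, an alternative chosen after seeing the data, edgeR called 0 genes higher and 11 lower. In that setting the calls ended for the lower genes Dazl (0.0955), Bnc2 (0.0564), Rab3gap2 (0.0623), Tex14 (0.0967), Smc1b (0.0564), Ptch1 (0.097) and Pdk1 (0.119) and for all 8 higher genes named here, with adjusted p from 0.0623 for Lrrc34 to 0.192 for Mfge8. Without KO replicate 3 they ended for Grn (0.0721), Mfge8 (0.0991), Rhox5 (0.0847), Tex14 (0.0721), Smc1b (0.0596), Pmaip1 (0.104), Ptch1 (0.114) and Pdk1 (0.104).

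Among the fixed lists, germ cell genes with promoters known to be methylated in somatic cells fell in KO. Of 38 tested members, 35 had a negative log2 fold change, with a median of -0.76. Over all genes 5 members were called lower (Mael, Dazl, Tdrd1, Tex14 and Smc1b) and 1 higher (Rhox5), and adjusted over the list alone 11 were lower and 1 higher. The list was called by camera (adjusted p = 5.98e-18) and remained so with an estimated correlation (adjusted p = 0.0321). The 24 piRNA pathway genes had a median of -0.64, with Mael and Tdrd1 called, 7 lower when adjusted over the list alone, and adjusted p = 0.0321 with an estimated correlation. The 39 meiosis genes had a median of -1.01, with Mael and Smc1b called and 5 lower adjusted over the list alone. The 27 genes of male germ cell fate had a median of -0.76, with Dazl, Tdrd1 and Tex14 called, and 8 lower and 1 higher adjusted over the list alone. These 2 lists were called at the preset correlation (adjusted p = 3.07e-07 and 1.12e-07), and each had adjusted p = 0.0585 with an estimated correlation. Their medians were -0.66 and -0.50 without WT replicate 1. The lists share members, among them Mael and Dazl, so their results are not independent.

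Smaller shifts in KO were seen in spermatogonial and glycolysis genes, each lost with an estimated correlation. The spermatogonial list had a median of -0.33 over 24 genes, with Uchl1 called, 1 lower adjusted over the list alone, and adjusted p = 0.0585 with an estimated correlation. Its median was -0.18 without WT replicate 1 and -0.69 without KO replicate 2, or -0.66 with members absent from a group at their bound. The glycolysis list was higher, with a median of 0.32 over 23 genes and adjusted p = 0.545 with an estimated correlation. Its only called member, the pyruvate dehydrogenase kinase gene Pdk1, was lower, and adjusted over the list alone 4 were higher and 1 lower. Without WT replicate 1 its median was 0.21 and its adjusted p 0.542, and without KO replicate 3 the adjusted p was 0.115. The DNA methylation enzymes were called at the preset correlation with Tet1 among them (median -0.12 over 26 genes, with Tet1 the called member, 3 lower adjusted over the list alone, and adjusted p = 0.0585 with an estimated correlation). Without Tet1, an alternative chosen after seeing the data, the list was not called (median -0.12 over 25 genes, camera adjusted p = 0.26), so its call rested on the mutated gene. With Tet1, the list had a median of -0.04 without WT replicate 1, and adjusted p = 0.113, 0.0535 and 0.0709 without WT replicate 2, KO replicate 2 or KO replicate 3. The other 18 lists were not called, the smallest adjusted p being 0.18 for pluripotency genes.

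The imprinted lists bear on the control regions named by the series. In KO the 26 paternally expressed genes had a median of -0.11 (camera adjusted p = 0.751) and the 28 maternally expressed genes a median of -0.08 (0.717), with 0 members called by edgeR over all genes. At an unadjusted p under 0.05, 2 paternally expressed members were lower and 1 higher, and 1 maternally expressed member was higher, while DESeq2 called 0 of either list. Peg3, a paternally expressed zinc finger gene, had 290 ± 93.9 CPM in KO against 522 ± 73.9 in WT (log2 fold change -0.85, SE 0.23, edgeR adjusted p = 0.13), and was lower when adjusted over the list alone. Neither imprinted list was called in HxD, with medians of -0.21 and -0.14, or in V, with 0.08 and -0.08. Gnas in V (log2 fold change 0.81, SE 0.22, edgeR adjusted p = 0.48) was higher when adjusted over the list alone, and it was the 1 maternally expressed member called by DESeq2 there. The median and the direction of the test differed in sign for the paternally expressed list in HxD and in V, and the mean of the maternally expressed list was positive in KO (0.24) and V (0.20). These counts do not tell the parental alleles apart.

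**Figure D2:**
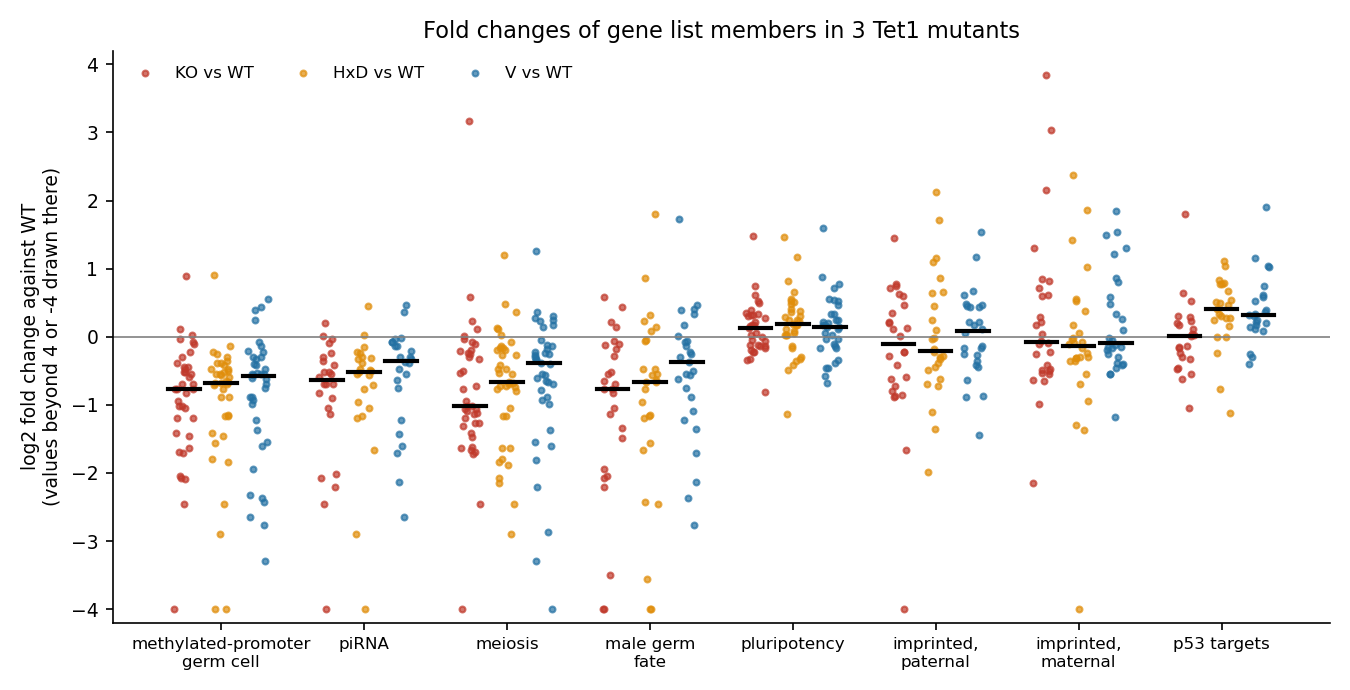
Log2 fold changes against WT (vertical axis, values beyond 4 or -4 drawn there) of the members of 8 gene lists in KO, HxD and V, with 1 point per gene and black lines at the medians. The medians of the list with methylated promoters were -0.76 in KO, -0.68 in HxD and -0.58 in V, while those of the imprinted lists lay between -0.21 and 0.08.

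The comparison of HxD with WT asks what happens when TET1 protein is present without catalytic activity. Mael fell to 16.3 ± 6.40 CPM against 121 ± 45.2 in WT (log2 fold change -2.89, SE 0.40, edgeR adjusted p = 0.000567), and Dazl to 793 ± 192 against 1754 ± 150 CPM (-1.15, SE 0.19, edgeR adjusted p = 0.00935). The p53 target Pmaip1, which encodes a protein that promotes cell death, also fell (-1.12, SE 0.21, edgeR adjusted p = 0.0258). Ulk1, a kinase that starts autophagy, and Mkx rose, with log2 fold changes of 1.11 (SE 0.20) and 1.71 (SE 0.33). These 5 were the genes called by edgeR, and 1211 had an unadjusted p under 0.05, where chance alone gives 735. DESeq2 called 213, and edgeR 67 without the low-count filter, 8 with 1 surrogate variable and 2 with these 2 genotypes alone. The count moved to 3 without WT replicate 1, 34 without WT replicate 2, 47 without HxD replicate 1 and 1 without HxD replicate 3. Mael was called under each of the 14 settings. Dazl lost its call without HxD replicate 3 (adjusted p = 0.0539), and so did Pmaip1 (0.14), Ulk1 (0.0539) and Mkx (0.0539). Pmaip1 and Mkx also lost theirs without WT replicate 1 (0.134 and 0.127), Ulk1 and Mkx without WT replicate 3 (0.173 for each) and without HxD replicate 2 (0.0604 for each). With WT 3 and V 3 set aside together the count was 2, and Dazl (0.0904), Ulk1 (0.238) and Mkx (0.261) lost their calls.

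In HxD the germ cell genes with methylated promoters were also lower, with 37 of 38 members negative and a median of -0.68. KO, HxD and V are compared with the same WT libraries, so their list results are not independent repeats. Over all genes 2 were called lower, and adjusted over the list alone 16 were lower and 1 higher. The list was called at the preset correlation (camera adjusted p = 1.95e-18) and kept its call with an estimated correlation (adjusted p = 0.0474). The piRNA list had a median of -0.51, with 5 lower adjusted over the list alone and adjusted p = 0.053 with an estimated correlation. Meiosis and male germ cell fate each had a median of -0.67 and adjusted p = 0.141 with an estimated correlation. The meiosis median was -0.43 without WT replicate 1. Adjusted over the list alone, 5 meiosis genes were lower, and 5 genes of male germ cell fate were lower and 1 higher. The pluripotency list was higher, with a median of 0.19 over 33 genes and adjusted p = 0.159 with an estimated correlation. Adjusted over the list alone 4 of its genes were higher and 1 lower, with examples in Tfap2c (0.82, SE 0.22) and Pou5f1 (0.55, SE 0.17). EdgeR called 0 of the list over all genes, with 7 higher and 2 lower at an unadjusted p under 0.05, and DESeq2 called 2, Pou5f1 and Dppa5a. The p53 list was higher (median 0.41 over 23 genes, adjusted p = 0.218 with an estimated correlation), although Pmaip1, its only called member, was lower, as it was over the list alone. Without WT replicate 1 the pluripotency and p53 lists had adjusted p = 0.055 and 0.159, and without HxD replicate 2 the p53 list had a median of 0.19 and 0.177. The other 19 lists were not called, the smallest adjusted p being 0.0542 for spermatogonial genes.

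The comparison of V with WT asks the same of a TET1 protein that stops at 5-hydroxymethylcytosine. EdgeR called 0 genes, with a smallest adjusted p of 0.171, while 890 had an unadjusted p under 0.05, where chance alone gives 735. DESeq2 called 84 and edgeR 32 without the low-count filter. The count was 10 without WT replicate 2, 2 without WT replicate 3 and 3 without V replicate 1. The germ cell genes of the other mutants had lower values here too. Dazl had 953 ± 255 CPM against 1754 ± 150 in WT (log2 fold change -0.88, SE 0.19, edgeR adjusted p = 0.19) and Mael 39.6 ± 11.7 against 121 ± 45.2 (-1.61, SE 0.38, edgeR adjusted p = 0.293). Pou5f1, the pluripotency gene behind the Oct4 reporter, had 516 ± 81.5 CPM against 316 ± 22.6 (0.71, SE 0.17, edgeR adjusted p = 0.293).

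Of the 38 germ cell genes with methylated promoters, 34 were negative in V, with a median of -0.58 and 0 called by edgeR over all genes. At an unadjusted p under 0.05, 13 were lower and 1 higher, and adjusted over the list alone 7 were lower and 1 higher. DESeq2 called 2, Dazl and Tex14. Camera called the list at the preset correlation (adjusted p = 2.36e-14), and it had adjusted p = 0.123 with an estimated correlation. The piRNA list (median -0.35), the meiosis list (-0.39) and the list of male germ cell fate (-0.37) were called at the preset correlation, with adjusted p = 0.18, 0.439 and 0.195 with an estimated correlation. Adjusted over the list alone 3, 2 and 4 of their members were lower. Without V replicate 3 the medians of methylated promoters and meiosis were -0.88 and -0.62. Without WT replicate 1 those of piRNA and male germ cell fate were -0.22 and -0.19, and without V replicate 2 that of male germ cell fate was -0.22. The meiosis list had adjusted p = 0.16 without WT replicate 1 and 0.0642 without V replicate 2. The p53 list was higher (median 0.32, adjusted p = 0.195 with an estimated correlation). EdgeR and DESeq2 called 0 of its members, also when adjusted over the list alone in edgeR, and 2 were higher at an unadjusted p under 0.05. Without WT replicate 1 its adjusted p was 0.189. The 8 mitochondrially encoded genes were higher (median 0.38, adjusted p = 0.569 with an estimated correlation). Their summed level was 27054 CPM in V 1 and 9532 to 18266 CPM in the other libraries. Without V replicate 1 their median was 0.02 with the direction of the test reversed, and without WT replicates 1 and 2 in turn their adjusted p was 0.378 and 0.109. Their median was 0.24 without WT replicate 1 and 0.59 without V replicate 2. The other 19 lists were not called, the smallest adjusted p being 0.062 for glycolysis. The number of lists called was 3 without WT replicate 1 and 11 without WT replicate 3.

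Set side by side, the 31 genes other than Tet1 that edgeR called in KO all had the same direction in HxD, 28 of them with an unadjusted p under 0.05, and all had it in V, 19 with such a p. These comparisons share the WT libraries, which alone makes fold changes resemble each other. In simulated unchanged groups, the 31 genes of smallest p had the same direction in a mean of 28.7 for KO and HxD and 29.0 for KO and V, reaching 31 in each. With an unadjusted p under 0.05 the simulated means were 13.7 and 13.9 and the highest values 23 and 20. Across 9271 genes, which are not independent replicates, log2 fold changes correlated with r = 0.666 for KO and HxD, 0.646 for KO and V and 0.61 for HxD and V, against means of 0.5, 0.498 and 0.499 for simulated unchanged groups. The covariances were 0.236, 0.206 and 0.198, against simulated means of 0.125, 0.124 and 0.124, which leaves differences of 0.112, 0.0816 and 0.0739. Called genes overlapped in 4 for KO and HxD (Mael, Dazl and Pmaip1 lower, Mkx higher), and in 0 for the pairs with V, where edgeR had called 0 genes in V. The simulated mean for KO and HxD was 0.02. Unchanged groups give almost no calls, so that mean could only lie near 0 and is no measure of a shared effect. At an unadjusted p under 0.01, 64 genes were higher and 61 lower in both KO and HxD, against simulated means of 19.5 and 4.54 and against 1.45 and 2.7 for independent lists. For KO and V there were 37 and 43, against simulated means of 18.7 and 4.58 and against 1.02 and 1.69. For HxD and V there were 42 and 26, against 17.3 and 4.92 and against 0.83 and 1.34. The simulations drew each gene independently around the same mean in all libraries, so they held no outlying library and no genes that vary together. In the data WT 3 lay far out, with a count of 0 in 107 genes averaging at least 8 CPM. A gene missed there looks higher in every mutant. With 3 WT libraries the controls could not be split, so part of the excess may come from the shared controls.

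**Figure D3:**
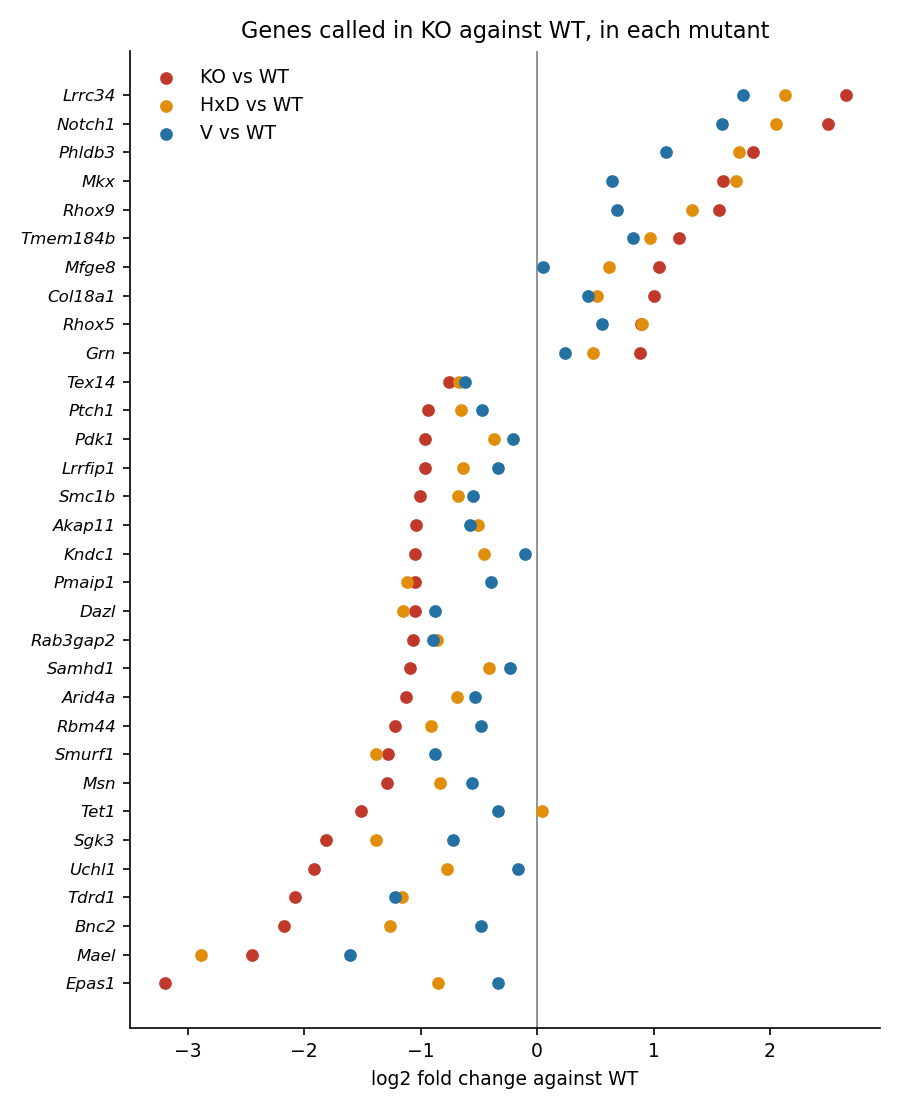
Log2 fold changes against WT (horizontal axis) of the 32 genes called in KO, with 1 line per gene and points for KO, HxD and V. Epas1 had -3.20 in KO, -0.85 in HxD and -0.34 in V, and Tet1 had -1.51, 0.04 and -0.34.

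The comparisons between mutants ask whether the alleles differ from each other. In each of them chance alone gives 735 genes at an unadjusted p under 0.05, so the counts of 686, 603 and 745 below show little or no excess. HxD exceeded KO in 1 gene, Tet1 itself (log2 fold change 1.56, SE 0.18, edgeR adjusted p = 7.87e-06), with 686 genes at an unadjusted p under 0.05, 99 called by DESeq2 and 8 by edgeR without the low-count filter. The count was 4 without KO replicate 2 and 14 without HxD replicate 1. V exceeded KO in 3 genes, with 603 at an unadjusted p under 0.05, 69 called by DESeq2, and 21 by edgeR without the low-count filter and 0 with these 2 genotypes alone. They were Tet1 (1.17, SE 0.17, edgeR adjusted p = 0.00222), Uchl1 (means of 142 against 42.2 CPM, 1.75, SE 0.28, edgeR adjusted p = 0.0038) and Epas1 (34.4 ± 15.1 against 4.76 ± 2.91 CPM, 2.85, SE 0.50, edgeR adjusted p = 0.0164). Epas1 had adjusted p = 0.0754 without KO replicate 1 and 0.0587 without V replicate 3. With WT 3 and V 3 set aside together the log2 fold changes were 0.94 for Tet1, 1.86 for Uchl1 and 2.79 for Epas1, and the calls ended (adjusted p = 0.111, 0.0966 and 0.227). The count was 16 without KO replicate 2, 7 without V replicate 1 and 18 without V replicate 2. Between V and HxD edgeR called 0 genes, with 745 at an unadjusted p under 0.05, 109 called by DESeq2 and 5 by edgeR without the low-count filter, and the count was 11 without HxD replicate 1, 1 without HxD replicate 3 and 3 without V replicate 2. For Dazl the 95% intervals of the differences were -0.48 to 0.29 for HxD over KO and -0.22 to 0.55 for V over KO, and for Mael -1.20 to 0.33 and 0.07 to 1.60 (edgeR adjusted p = 1 for each).

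Between mutants 11 list calls were made at the preset correlation, and none with an estimated correlation. HxD over KO gave 2 lists at the preset correlation, DNA methylation enzymes (median 0.06, Tet1 called, 1 higher adjusted over the list alone, adjusted p = 0.187 with an estimated correlation) and p53 targets (0.29, 0.226, with Ccng1, named after its values were seen, higher over the list alone). V over KO gave 5, namely meiosis (0.32, adjusted p = 0.512 with an estimated correlation), piRNA (0.34, 0.463), p53 (0.28, 0.345, with Ccng1 and Pmaip1 higher over the list alone), macrophage markers (4.10, or 3.60 with members absent from KO at their bound, 0.408) and mitochondrially encoded genes (0.53, 0.463). V over HxD gave 4, namely Sertoli markers (2.42, adjusted p = 0.727 with an estimated correlation), macrophage markers (5.50, or 4.04 at the bound), mitochondrially encoded genes (0.55) and Y-linked genes (-0.34), each with that p. Without Tet1 the enzyme list of HxD over KO was not called (median 0.06, camera adjusted p = 0.269). With Tet1 its median was 0.11 without KO replicate 2 and 0.02 without HxD replicate 1, and it had adjusted p = 0.0594, 0.0794, 0.11 and 0.0696 without KO replicates 2 and 3 and HxD replicates 1 and 2 in turn, and the p53 list of HxD over KO had 0.0696 without HxD replicate 2. For V over KO, meiosis had 0.201, 0.175, 0.0638 and 0.428 without KO replicates 1 and 3 and V replicates 1 and 3, piRNA 0.156 and 0.245 without KO replicate 1 and V replicate 3, and the mitochondrial list 0.628 without V replicate 1. Without KO replicates 1, 2 and 3 and V replicates 1 and 3 in turn, the meiosis median was 0.14, 0.54, 0.11, 0.12 and 0.08, the last 2 becoming 0.33 and 0.23 with members absent from a group at their bound. In the same order the macrophage median at the bound was 3.61, 4.57, 3.51, 4.76 and 3.39, over 13, 13, 13, 11 and 11 tested members instead of 6. The piRNA median was 0.14, 0.18 and 0.13 without KO replicate 1, V replicate 1 and V replicate 3, and the mitochondrial median 0.13 without V replicate 1. For V over HxD, the mitochondrial list had 0.112 and 0.363 without HxD replicate 1 and V replicate 1, and the Y-linked list 0.25, 0.0702 and 0.363 without HxD replicates 1 and 2 and V replicate 1. The mitochondrial median was 0.32, 0.90 and 0.18 without HxD replicate 1, HxD replicate 3 and V replicate 1, and the Y-linked median -0.12 and -0.58 without HxD replicate 1 and V replicate 2. The macrophage median at the bound was 1.97 and 2.17 without HxD replicates 1 and 3. Sertoli markers had 0.0535 without HxD replicate 1, and without V replicate 2 a median of 0, or 0.04 at the bound, with the direction of the test reversed. The number of lists called for HxD over KO was 5 without KO replicate 1, 1 without KO replicate 2, KO replicate 3 or HxD replicate 1, and 0 without HxD replicate 2. It was 9 for V over KO without KO replicate 2, and 2 for V over HxD without V replicate 1.

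Markers of other gonadal cell types were measured beside these results. Sertoli markers, from the somatic cells that surround germ cells, summed to 902 CPM in V 2, 510 in WT 3 and 224 to 319 in the other libraries. Granulosa markers, from somatic cells of the ovary, summed to 96.8 CPM in V 2 and 15.5 to 49.6 in the other libraries, the highest of these being WT 3. Macrophage markers summed to 54.9 CPM in V 2 and 20.8 in V 3, above each of the other libraries. Endothelial markers summed to 45.6 ± 10.2 CPM in WT, 41.5 ± 23.8 in KO, 78.3 ± 7.93 in HxD and 66.4 ± 23.9 in V. The higher HxD sum came mostly from 1 member, Mmrn2 (32.3 ± 11.7 CPM in HxD against 2.24 ± 1.65 in WT, log2 fold change 3.85, SE 0.98, edgeR adjusted p = 0.212). Without Mmrn2 the sums were 43.3, 39.0, 46.0 and 62.7 CPM. The 11 tested markers, Mmrn2 included, had a median of -1.09 in HxD against WT. The direction of the test was up, opposite to that median (camera adjusted p = 0.927). Leydig markers summed to 315 ± 9.71, 327 ± 53.5, 255 ± 29.4 and 276 ± 9.36 CPM. The lists for spermatids (medians -0.10, -0.24 and 0.51 in KO, HxD and V against WT), cell cycle (-0.02, -0.02 and 0.06), cell cycle arrest (0.23, 0.11 and 0.46), interstitial cells (0.32, 0.29 and -0.12), immediate-early genes (0.08, -0.06 and 0.01) and TGF-beta and Nodal signalling (0.03, 0.02 and 0.01) were not called by camera in any comparison. Those for Leydig, endothelial, erythroid and granulosa cells were not called either, and Sertoli, macrophage and Y-linked genes were not called against WT. Xist, made from an inactive X chromosome, stayed between 0 and 3.89 CPM.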

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

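All tests of explanations in this part were chosen after the results were seen, except the counts over other splits of the samples and the test of slower progress of the germ cells.

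The effects of the alleles differed in 4 tests of the difference itself. Uchl1 was higher in V than in KO by a log2 difference of 1.75 (edgeR adjusted p = 0.0038) and Epas1 by 2.85 (edgeR adjusted p = 0.0164). HxD over KO had the same direction without a call, with 1.15 for Uchl1 (edgeR adjusted p = 0.489) and 2.34 for Epas1 (edgeR adjusted p = 0.21). V over HxD was 0.61 for Uchl1 and 0.51 for Epas1, also not called, so the difference is not particular to V. Tet1 was higher in HxD than in KO by 1.56 (edgeR adjusted p = 7.87e-06) and higher in V than in KO by 1.17 (edgeR adjusted p = 0.00222).

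For Uchl1 and Epas1, a local effect of passenger DNA linked to the Tet1 allele is argued against, since 0 of the 2 genes lie on chromosome 10. Indirect effects of such DNA, and differences in unlinked background, stay open. Among 200 tested genes around Tet1, 1 was called in KO against WT. An unadjusted p under 0.05 was held by 9% of them and by 8.3% of all genes. Fewer endothelial cells in the KO sorts, which could lower Epas1, stay open: the 11 endothelial markers had a median difference of 0.36 (p = 0.474 with an estimated correlation), but they lay near the floor, with a median average log2 CPM of 1.36, and exclude nothing. The Oct4-GFP gate should remove such cells. No biological explanation was tested. With WT 3 and V 3 set aside the differences were 1.86 and 2.79, and both calls were lost.

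Germ cell genes with methylated promoters were lower in KO and HxD, with the same direction in V, and technical explanations and slower progress of the germ cells were weighed beside loss of TET1 activity. Fewer germ cells among the sorted cells, as the only cause, would lower other germ cell genes alike. Instead 33 pluripotency and early germ cell genes had medians of 0.13, 0.19 and 0.15 in KO, HxD and V. They lay above the list by at least 0.73 (SE 0.14, from resampling genes as if independent, not libraries). They include Pou5f1, the gene behind the sort reporter, and may shift with germ cell progress. A smaller share of germ cells combined with slower progress therefore stays open. Uneven gene detection or gene length bias is argued against only as far as it follows expression and length. Of 10000 random lists matched on expression, or on expression and length, 0 had a median as low in any mutant. The medians of the lists matched on expression centred on -0.01 in each mutant. Their genes were drawn singly, while members of the lowered list vary together, so the 0 does not measure chance. Slower progress of the germ cells may contribute and stays open: the 59 other members of the male fate, piRNA and meiosis lists had medians of -0.65, -0.49 and -0.25 in KO, HxD and V (p = 0.049, 0.136 and 0.306 with an estimated correlation). An unlabelled batch that sets the WT libraries apart also stays open, because no batch is labelled. WT lay apart from all mutants on 0 of the first 3 principal components. However, WT 3 lay far out on PC2 and V 3 on PC3, and components led by single libraries could hardly show such a batch. Log2 fold changes against the shared WT libraries also fell with exonic length in KO, HxD and V (Spearman -0.182, -0.162 and -0.256), and the cause was not tested.

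Sertoli markers were high in V 2, where 20 of 27 were at their highest. Amh, a hormone gene of Sertoli cells chosen after its values were seen, had 216 CPM in V 2 and 59.6 in WT 3, and granulosa (96.8 CPM) and macrophage markers (54.9 CPM) were also highest in V 2. Whether Sertoli cells carried over in the sort of V 2 are the source stays open, since the list was singled out for this library and its markers vary together. The Oct4-GFP gate should remove such cells. No biological explanation was tested, since no label sets this library apart.

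Each comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05. For KO against WT the real split called 32 genes and the highest other 0, so 1 split reached the real count. For HxD against WT the values were 5 and 7, with 2 splits at or above the real count. For HxD against KO they were 1 and 0, with 1 split, and for V against KO 3 and 1, with 1 split. For V against WT they were 0 and 0, and for V against HxD 0 and 1, so that all 10 splits reached the real count. These are edgeR counts. In those last comparisons 890 and 745 genes had an unadjusted p under 0.05, where chance alone gives 735, and DESeq2 called 84 and 109.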

How the results depend on the processing

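All alternatives here were planned except setting WT 3 and V 3 aside together and leaving Tet1 out of the DNA methylation enzymes, which were chosen after seeing the data. Counts of called genes are given in the order KO, HxD and V against WT, HxD against KO, V against KO and V against HxD, and edgeR gave 32, 5, 0, 1, 3 and 0. They depended on the settings, while directions rarely did. Of 31 gene calls followed through 14 settings each, 7 were kept in every setting (Tet1 in KO against WT and HxD against KO, Mael in KO and HxD, and Uchl1, Sgk3 and Epas1 in KO), and 0 of 434 values reversed, with 104 no longer past the threshold. Of 30 list calls, 3 were kept in all 10 settings (methylated promoters in KO and HxD, piRNA in KO), and of 300 values 86 kept their direction without passing the threshold and 2 reversed.

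DESeq2 gave 212, 213, 84, 99, 69 and 109 genes, and it also made 62 calls on simulated data where nothing had been changed. Without the low-count filter there were 148, 67, 32, 8, 21 and 5, and with a stricter filter 19 for KO against WT. With only the 2 genotypes compared, fewer samples set the spread. The counts were then 12 for KO against WT, 2 for HxD against WT and 0 for V against KO. In the fit to all libraries V against KO had 603 genes at an unadjusted p under 0.05, where chance alone gives 735, and DESeq2 called 69. With 1 surrogate variable the counts were 18 (2 higher and 16 lower) and 8 for KO and HxD against WT. That variable mainly followed WT 3, at -0.892. With WT 3 and V 3 set aside they were 11, 2 and, for V against KO, 0. RLE scaling and a minimum fold of 2 kept every count within 1.5 times. The cause was not tested for the other shifts.

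The replicate numbers did not pair the samples: 1 of 18 same-numbered pairs had deviations correlated above 0.1, and 4 of 12 libraries correlated best with their own number. With a replicate block the counts of genes were nevertheless 104, 45, 8, 8, 16 and 2, and that of lists was 1 for HxD against KO. The cause was not tested.

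Lists called at the preset correlation numbered 7, 6, 6, 2, 5 and 4. With an estimated correlation they numbered 2, 1, 0, 0, 0 and 0, and with fry 2 for HxD against WT and 0 for V against WT and for each pair of mutants. With WT 3 and V 3 set aside they were 12 for V against WT, 1 for HxD against KO and 3 for V against KO. Overlaps of genes at an unadjusted p under 0.01 were 125, 80 and 68 for KO with HxD, KO with V and HxD with V, against 4, 0 and 0 called genes. That threshold admits more genes by construction. Without Tet1 the DNA methylation enzymes were not called in KO against WT (camera adjusted p = 0.26) or HxD against KO (0.269), so those 2 calls rested on the mutated gene.

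Leaving out each library in turn gave 15 to 95 genes for KO against WT, 1 to 47 for HxD against WT, 0 to 10 for V against WT, 1 to 14 for HxD against KO, 2 to 18 for V against KO and 0 to 11 for V against HxD. Lists ranged from 5 to 9, 5 to 7, 3 to 11, 0 to 5, 4 to 9 and 2 to 6. Some values reversed: the mitochondrial gene ND4 in HxD against WT was 0.07 without HxD replicate 1 (-0.27 with all libraries, and -0.63 without HxD replicate 3), and Tet1 in HxD against WT was -0.09 without HxD replicate 2 and up to 0.15 without HxD replicate 3. The mitochondrially encoded list in V against WT had a median of 0.02 without V replicate 1 and up to 0.59 without V replicate 2. The Sertoli list in V against HxD had a median of 0 without V replicate 2, or 0.04 with members absent from a group at their bound, and up to 2.92 without V replicate 1. V 1 held the highest summed level of the mitochondrial list and V 2 that of the Sertoli list, while the cause was not tested for ND4 and Tet1. The planned split of the WT libraries was not run. Libraries with the fewest detected genes, WT 3 with 11529 and V 3 with 12100, limit what can be read for weakly expressed genes.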

Other observations

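The pooled comparison of WT with all mutants and the gene families in this part were chosen after the results were seen.

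The summed level of germ cell genes with methylated promoters separated WT from every mutant library. Their summed level was 6888 ± 740 CPM in WT (SD, n = 3), 4425 ± 331 in KO, 4349 ± 710 in HxD and 4814 ± 750 in V, and the lowest WT library (6325) lay above the highest mutant library (5624). The exact permutation p for 3 libraries against 9 was 0.00455, the smallest this design allows, and 0.0394 after Benjamini-Hochberg adjustment over the lists. The piRNA and male germ cell fate lists gave that p too, and they share members with this list. Abundant members weigh most in such sums. Dazl alone had 1605 to 1906 CPM in WT libraries and 576 to 1172 CPM in mutant libraries. The list had already been found lower in these same libraries, so the permutation p adds no independent evidence.

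The X-linked Rhox homeobox cluster had summed levels of 223 to 367 CPM in WT libraries, 477 to 708 in KO, 542 to 695 in HxD and 348 to 604 in V. These sums came mostly from Rhox5, Rhox6 and Rhox9, while the 14 tested members had medians of only 0.14 (SE 0.55), 0.53 (SE 0.57) and 0.47 (SE 0.39), with 9, 8 and 9 of them positive, and p = 0.147, 0.0501 and 0.278 with an estimated correlation in KO, HxD and V. Rhox2c, Rhox4c, Rhox2g, Rhox7a and Rhox10 had negative values in KO, Rhox2c with an unadjusted p of 0.0192 (edgeR adjusted p = 0.484). Rhox6 had log2 fold changes of 1.82, 1.86 and 1.53 (edgeR adjusted p = 0.13, 0.256 and 0.579), and near-identical members of the cluster can share reads.

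Nuclear genes of the respiratory chain, 89 in number, had medians of 0.24, 0.18 and 0.26 in KO, HxD and V (p = 0.182, 0.153 and 0.0808 with an estimated correlation), and 84 ribosomal protein genes 0.10, 0.11 and 0.24 (0.599, 0.434 and 0.191). V 1 stood apart in the summed levels, with 58996 CPM for ribosomal proteins against 38834 to 48108 in the other libraries, 43624 and 41591 of these in V 2 and V 3. It was also highest for the respiratory chain, at 15715 against 11706 to 14298 CPM, and for mitochondrially encoded genes, at 27054 CPM. Across 9002 genes, which are not independent replicates, the Spearman correlation of log2 fold change with exonic length was -0.182 in KO, -0.162 in HxD and -0.256 in V.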
